A study of Mus musculus with 2 samples.

How the data were processed

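Single cells from the dissected Achilles tendon enthesis of SKG mice were profiled on the droplet platform of 10x Genomics, in 1 library from non-tail suspension and 1 from tail suspension. Per the labels, the tissue was digested with collagenase, strained, treated to lyse red cells, depleted of dead cells and sequenced on an Illumina instrument. The deposited files hold UMI counts per gene and barcode, made by the authors before deposit. The submitters' processing notes name Cell Ranger 5.0.1 and the genome build GRCm38, without saying which step each served. The values are whole numbers, every barcode has at least 500 UMIs, and no normalization was found.

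Mean depth per barcode was close in the 2 libraries, at 10662 and 10718 UMIs, while the medians differed. Whether the libraries were aggregated or brought to equal depth before deposit is not stated in any source. If they were, the totals are not the sequencing depth. The files list 32285 genes with Ensembl IDs and symbols, and 32158 of the IDs matched the GENCODE annotation on GRCm38, from which positions were taken.

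Cells were kept with at least 300 genes and at most 20% mitochondrial UMIs. In the non-tail suspension library 91 barcodes had fewer genes and 468 had a higher mitochondrial share, and in the tail suspension library 268 and 948. Doublets were then called per library with Scrublet as implemented in scanpy, with an expected rate of 0.8% per 1000 barcodes (9.14% and 12.4%). Its automatic threshold removed 133 (1.21%) and 492 (3.40%) cells. These shares are below the expected rates, so doublets may remain. Clusters 4, 25 and 27 have median depths of 26344, 35426 and 39096 UMIs, and whether doublets add to these was not tested. After filtering, 10814 cells with 118098425 UMIs and 13991 cells with 156580161 UMIs were kept. Their median mitochondrial shares were 1.46% and 3.10%.

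Both libraries were clustered together without integration: counts per 10000 on a log scale, 2000 variable genes chosen within each library, 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0 with 2 iterations, which gave 32 clusters. Cell type annotations by the authors were not used here. Clusters were named "X-like" from fixed markers of 28 cell classes. For each cluster, genes detected in at least 20% of its cells were ranked by fold over the median of the other clusters with a pseudocount of 10 CPM. The name is that of the class with the most markers among the top 10 genes and then the top 50, with at least 3 in the top 50. Clusters that failed this, or whose top 10 genes held more markers of another class, stayed unnamed and are given by number. The scoring was set after seeing the data, as was the definition of immune clusters as those with more than 100 CPM of Ptprc. Fibroblast-lineage cells are the clusters named tenocyte-, sheath or lining fibroblast- or fibroblast-like.

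For each class with at least 100 cells in both libraries, raw UMIs were summed per library and expressed as CPM, and the log2 ratio of tail suspension over non-tail suspension was taken; 13 classes and clusters were compared. Shares carry exact Clopper-Pearson intervals, CPM exact Poisson intervals and ratios exact conditional binomial intervals, all at 95%. They cover counting error only. Cells are not replicates, so no test, p-value or count of changed genes was made. A gene with 0 UMIs in a library was set to 3 UMIs to rank its ratio, and the limit of its exact interval is given as the bound.

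Named genes were chosen by a fixed rule. They had at least 100 UMIs in the class, and at least 50 CPM and 10% of cells with a UMI in the library where they were higher. Mitochondrial, ribosomal protein, haemoglobin and predicted genes and markers of other classes were left out. The genes with the largest ratios in each direction that kept their sign under median-of-ratios scaling and in thinned cells were taken: 10 and 10 in the fibroblast lineage, 5 and 5 in all kept cells and in each fibroblast class, and 3 and 3 in each other class. Sdc1, Sox5 and examples from the gene lists were named besides. Members of 21 gene lists with at least 20 UMIs in a class count as measured. A list's median log2 ratio was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. Some genes, such as Vcam1, Vegfa and Spp1, are in more than 1 list, Sox5 is in the cartilage list, and Sdc1 is both a sheath fibroblast marker and a member of the syndecan list.

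The cell filters, clustering settings, marker genes, gene lists, rule for named genes and other settings to be tried were fixed before the data were examined. The alternatives were median-of-ratios scaling, CPM without a few abundant gene families, cells thinned to 1000 or 2000 UMIs, a mean over cells, gene minimums of 500 and 1000, a mitochondrial limit of 10%, doublets kept, Leiden resolutions of 0.5 and 2.0, each library clustered on its own, and a minimum of 2 UMIs for detection. The limits of percentiles 2.5 and 97.5, the lineage with clusters 4 and 25 added, and the mean of ratios within clusters of at least 50 cells in each library were chosen after seeing the data. That mean took genes without a minimum of UMIs in each cluster. A gene undetected in a cluster is set to 3 UMIs in both libraries, so its ratio there is negative where the tail suspension library has more UMIs.

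The ratio, its interval and the list percentile were tested on simulated data with the depths of the fibroblast lineage over 13125 genes. All 100 genes changed 2-fold had the right direction and 94.0% of their intervals held the true ratio, against 95.0% at 4-fold and 95.3% for 12925 unchanged genes. All 21 lists of unchanged genes lay inside the percentile limits, and a list raised 2-fold had a median of 0.99. The counts were drawn independently around 1 shared profile. The check therefore does not cover genes that vary together or a difference in cell makeup, either of which can move a real list. Classes with fewer than 100 cells in either library were left out of the expression comparisons by class. Among them was the sheath or lining fibroblast-like class with 84 cells without suspension, for which class values are given only for Sdc1 and Sox5. Its single cluster had at least 50 cells in each library, so it entered the comparisons by cluster and the means within clusters. The work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9 and matplotlib 3.10.9.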

Results

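The data are single-cell RNA counts from the Achilles tendon enthesis, where the tendon inserts into bone, of SKG mice, a strain with a Zap70 mutation that is prone to autoimmune arthritis and enthesitis. In tail suspension a mouse is held by the tail so that its hindlimbs carry no load. There was 1 library from non-tail suspension and 1 from tail suspension, and how many animals each pooled is not given. Their age, their sex and whether arthritis was induced are not given either. The non-tail suspension library held 11430 barcodes and 121868851 UMIs (unique transcript molecules), with a median of 4482 UMIs per barcode. The tail suspension library held 15545 barcodes and 166606774 UMIs, with a median of 7823. After filtering, 10814 and 13991 cells were kept, with medians of 4649 and 8362 UMIs. Expression is given as CPM, the UMIs of a gene scaled to the same total in each library. Xist, the RNA of the inactive X chromosome, was at 464 and 697 CPM, and 4 Y-linked genes together had 2 and 4 UMIs. With no replicates there is no test of any difference, and all intervals are exact 95% intervals that cover counting error only.

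The comparison of cell types asks which cells made up the unloaded and the loaded enthesis preparation. Immune cells, which express the pan-leukocyte gene Ptprc, were 79.0% (95% Clopper-Pearson interval 78.2 to 79.7) of kept cells without suspension and 47.4% (46.6 to 48.3) with it. Neutrophil-like cells, the short-lived phagocytes of acute inflammation, were 48.6% (47.7 to 49.6) against 9.53% (9.05 to 10.0). Fibroblast-lineage cells, the matrix-producing clusters named tenocyte-like, sheath or lining fibroblast-like and fibroblast-like, were 12.7% (12.1 to 13.4) against 43.1% (42.3 to 43.9). Monocyte-like cells were 3.03% without suspension and 12.1% with it.

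Among immune cells alone, neutrophil-like cells were 61.6% without and 20.1% with suspension, monocyte-like cells 3.84% and 25.4%, and macrophage-like cells 12.6% and 20.6%. T cell-like cells were 6.94% and 13.4% of immune cells, and B cell-like cells 1.19% and 5.03%. Over all kept cells the macrophage-like share was 9.96% and 9.75%, an order that depended on the settings. It was 11.2% and 15.6% with at least 500 genes, and 15.9% and 10.3% with at least 1000. The order also turned with doublets kept (12.16% and 12.26%), with at most 10% mitochondrial UMIs (8.37% and 9.14%) and with each library clustered on its own (7.13% and 7.55%). It held at resolutions 0.5 and 2.0. Osteoclast-like cells, which resorb bone, numbered 51 without suspension and 3 with it; how much bone or marrow was dissected with the tendon is not given. Blood endothelial-like cells numbered 86 and 169, mural-like cells of the vessel wall 97 and 392, lymphatic endothelial-like cells 12 and 151, and mast or basophil-like cells 10 and 68.

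Clusters 4, 11, 19 and 25 stayed unnamed. Clusters 4 and 25 carried fewer than 3 fixed markers of any class, and in clusters 11 and 19 the 10 leading genes favoured a class other than the one with most markers. Cluster 4, led by Mmp3, Cxcl5, Col1a1 and Cxcl12, was 5.22% of kept cells without suspension and 0.793% with it, and cluster 25, led by Cxcl5, Prg4 and Timp1 with the proliferation genes Ube2c and Top2a, was 1.13% and 3.12%. Counting both with the fibroblast lineage gives 19.1% and 47.0%, a grouping chosen after seeing the data. Cluster 11, led by the MHC class II genes H2-Ab1 and Cd74 with Clec4n and Lyz2, was 8.44% and 3.45%, and cluster 19, led by the granule genes Prtn3 and Mpo, the keratinocyte gene Lgals7 and proliferation genes, was 0.934% and 1.25%. Neutrophils hold little RNA, so the gene minimum matters: with at least 1000 genes per cell their share was 25.8% and 5.91%. Dissociation and dead cell removal act before counting, so these are shares of recovered cells.

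**Figure D1:**
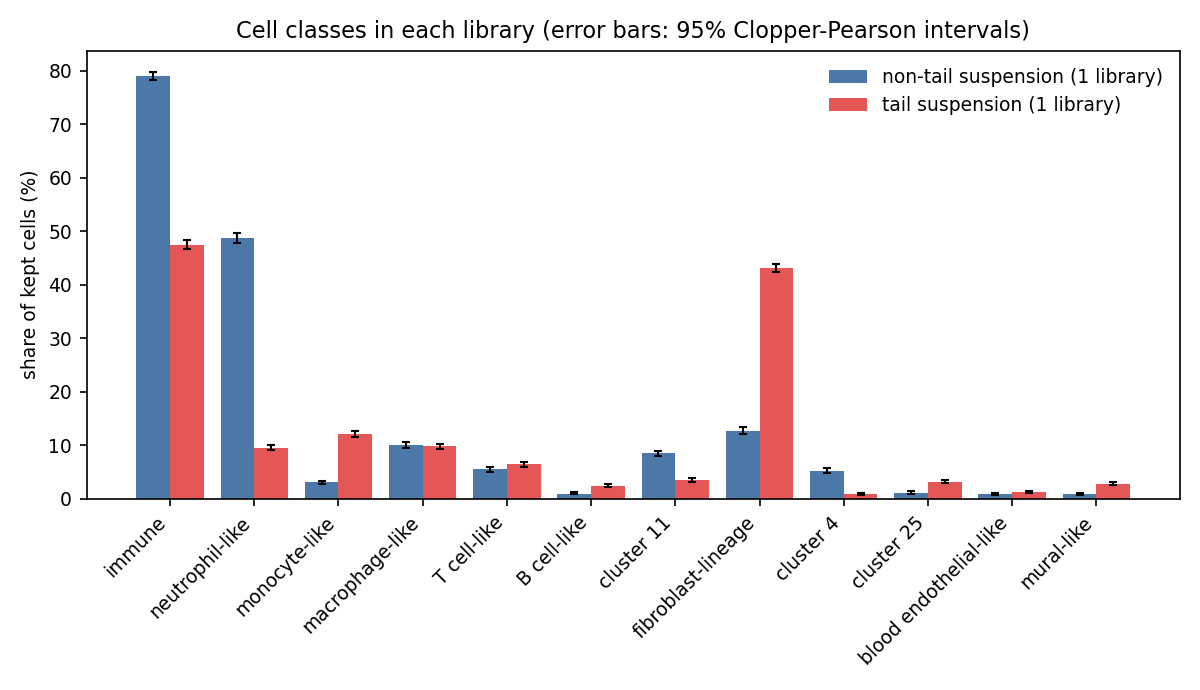
Share of kept cells (%) in each cell class for the non-tail suspension and tail suspension libraries (1 library each), with 95% Clopper-Pearson intervals as error bars. Neutrophil-like cells are at 48.6% and 9.53%, and fibroblast-lineage cells at 12.7% and 43.1%, so the larger share lies in opposite libraries.

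Within the fibroblast lineage, 976 tenocyte-like, 316 fibroblast-like and 84 sheath or lining fibroblast-like cells came from the non-tail suspension library, and 714, 4200 and 1117 came from the tail suspension library. Tenocytes are the resident cells of tendon, and sheath or lining fibroblasts coat its gliding surface. The clusters behind these names differed between libraries: cluster 0, led by Col1a1, Thbs4, Sfrp2 and Comp, held 67.7% of the lineage without suspension and 1.89% with it. The genes that lead these clusters are among those that differed between libraries, so no order of the sub-class shares is read. The names also depended on the settings: the sheath or lining fibroblast-like class held 734 non-tail suspension cells at resolution 0.5, 662 with doublets kept and 0 with that library clustered on its own. The tenocyte-like share, 9.03% and 5.10%, was 10.6% and 17.3% at resolution 0.5.

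The main comparison asks how expression in fibroblast-lineage cells differed between the unloaded and the loaded enthesis, over 1376 cells and 33204993 UMIs without suspension and 6031 cells and 82768720 UMIs with it. Interferon-inducible genes were lower in the tail suspension library, with all 19 measured members of the interferon list lower and a median log2 ratio (tail suspension over non-tail suspension) of -1.90. All 15 antigen presentation genes were lower as well, with a median of -1.59. Tendon matrix and cartilage genes were mostly lower, bone formation genes were mostly higher, and lubricin (Prg4), the lubricating proteoglycan of gliding surfaces, was at 31749 CPM against 4353. Il6, an inflammatory cytokine, was higher with suspension, at 653 against 171 CPM.

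Of the 10 named genes higher with suspension, Galnt15 (ENSMUSG00000021903, GRCm38 chromosome 14, 32028989 to 32062197), an enzyme family member that starts mucin-type glycosylation, had the largest log2 ratio, 3.30 (interval 3.13 to 3.48), from 8.73 to 86.2 CPM. Clic5, an intracellular chloride channel protein, followed at 3.25 (3.11 to 3.39). Prg4 (ENSMUSG00000006014, chromosome 1, 150449412 to 150466165) had a ratio of 2.87 (2.86 to 2.87). T cell-like cells also held Prg4, at 87.0 and 1445 CPM, so free RNA from other cells may add to this ratio. How much it adds was not measured. Scd1, the desaturase that makes monounsaturated fatty acids, was at 72.3 and 443 CPM. Snhg3, a small nucleolar RNA host gene, was at 33.2 and 177, and Vldlr, a lipoprotein receptor, at 12.0 and 60.9. Igfbp3, which binds insulin-like growth factors, was at 79.8 and 386, with a log2 ratio of 2.27. Cp, the copper-binding ferroxidase ceruloplasmin, had a ratio of 2.12 and Abca8a, a lipid transporter family member, a ratio of 2.06. Il6 (ENSMUSG00000025746, chromosome 5, 30013114 to 30019981) had a ratio of 1.94 (1.90 to 1.98).

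Of the 10 named genes lower with suspension, Megf6 (ENSMUSG00000057751, chromosome 4, 154170730 to 154275713), which encodes a protein with many EGF-like domains, had a log2 ratio of -4.75 (-4.98 to -4.53). Matrix genes among them were Cpxm2, a tenocyte marker of the carboxypeptidase family, at -4.11, Col8a2 at -3.87, the microfibril gene Mfap4 at -2.92 and the fibrillar collagen gene Col11a1 at -2.88. Kcnj15, a potassium channel, was at 78.8 and 7.24 CPM, and Ddah1, which breaks down inhibitors of nitric oxide synthesis, was at 152 and 19.3. Interferon-inducible genes made up the rest. Igtp, an immunity-related GTPase, had a ratio of -3.29 (-3.42 to -3.15), and Cxcl9 (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079), which attracts T cells, had -3.05 (-3.12 to -2.99). Bst2, the tetherin that holds budding viruses on the cell, had -2.82 (-2.88 to -2.76).

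The 20 genes were named on condition that their sign held under median-of-ratios scaling and in thinned cells, and all of them kept it in the other 9 settings. Prg4, Clic5 and Scd1 lead the sheath or lining fibroblast-like cluster, Igfbp3 leads 2 fibroblast-like clusters, and Cp and Abca8a lead another. As a mean of ratios within clusters, an alternative chosen after seeing the data, most of the named genes were nearer to 0: the higher genes ranged from 0.73 for Vldlr to 2.54 for Galnt15, with Prg4 at 1.88 and Il6 at 1.11. The lower genes ranged from -0.41 for Col11a1 to -3.28 for Igtp, with Megf6 at -1.72, Cxcl9 at -2.39 and Bst2 at -2.85.

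**Figure D2:**
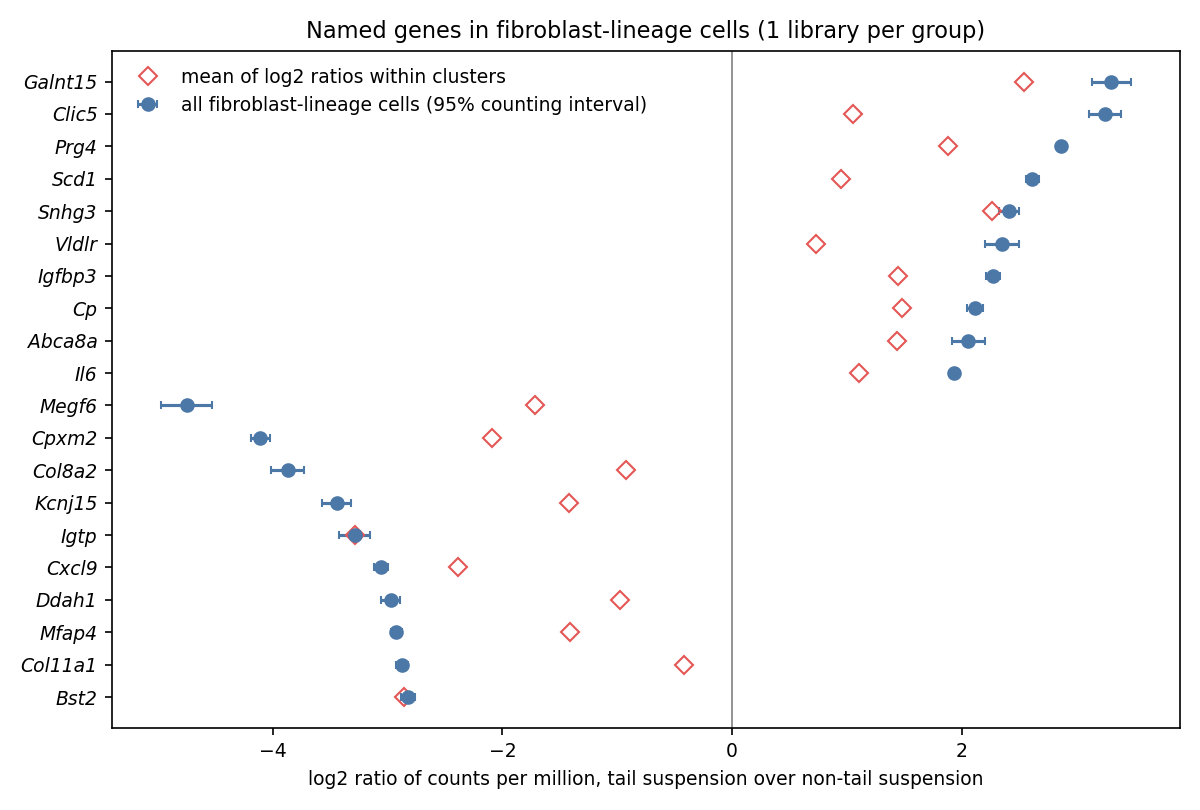
Log2 ratio of CPM (tail suspension over non-tail suspension, 1 library each) of the 20 named genes in fibroblast-lineage cells; filled points are all cells summed with 95% counting intervals, open diamonds the mean of ratios within clusters. Igtp, Bst2 and Snhg3 have nearly the same ratio both ways, while Megf6, Col8a2 and Col11a1 are nearer to 0 within clusters.

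The interferon and antigen presentation lists had medians below 0 in each of the 6 fibroblast-lineage clusters with enough cells; clusters 21 and 29, with 44 and 7 cells without suspension, were not run. Single members differed, and 4 of 13 antigen presentation genes were higher in cluster 2. In the pooled lineage the GTPase gene Iigp1 had a log2 ratio of -2.63 and Isg15, a ubiquitin-like modifier, -2.51. Antigen presentation genes included the peptide transporter Tap1 at -2.32, the immunoproteasome subunits Psmb9 at -2.24 and Psmb8 at -2.07, and the MHC class I gene H2-K1 at -1.55. Both lists lay below all 10000 random lists matched on expression. As medians of the members' mean ratios within clusters they were -2.18 and -1.80. The MHC class II genes in that list, such as Cd74 at 246 and 61.5 CPM, were at a level that free RNA from immune cells reaches, and for the antiviral gene Rsad2 (9.31 and 1.23 CPM, log2 ratio -2.92) such RNA could give 57.6% of the gap. The neutrophil and monocyte activation list, with 16 of 19 members lower and a median of -1.33, was likewise below all random lists. Its members include Il1b at 127 and 29.9 and the chemokine gene Ccl3 at 29.9 and 4.59, transcripts of myeloid cells. S100a9, an abundant neutrophil transcript, was present in the same cells at 839 and 469.8.

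Inflammatory targets outside the interferon pathway went different ways by cluster. Pooled, the IL-17, TNF and NF-kB list had 14 members higher and 10 lower with a median of 0.06, at percentile 72.7 of random lists. In tenocyte-like cluster 0 it was lower for 18 of 24 members (median -0.69), and in fibroblast-like cluster 1 higher for 17 of 24 (median 0.45). Lcn2, an iron-sequestering antibacterial protein, was higher at 2052 against 737 CPM, and the NF-kB inhibitor gene Nfkbia was lower at 685 against 1522. The IL-23/IL-17 lymphocyte axis had 10 of 13 members higher with a median of 0.43 (percentile 92.5), led by the epidermal growth factor family ligand Areg at 1.87. The list's median was above 0 in 5 of 6 clusters, from 0.05 to 0.69, and was -1.41 in cluster 7. With each gene averaged within clusters it was -0.52, but that average also took members with too few UMIs in a cluster to count as measured. Such members come out negative where the tail suspension library holds more UMIs. The value therefore cannot be set against the cluster medians, and the list's direction is not settled. These lymphocyte genes stood near the floor in fibroblast-lineage cells.

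Extracellular matrix genes were mostly lower in the pooled lineage, with values that differed by cluster. Tendon matrix and tenogenic genes were lower for 23 of 26 members with a median of -1.01, among them type I collagen gene Col1a1 at 16059 and 5127 CPM, Thbs4 (a matrix glycoprotein) at -2.12 and the collagen-binding proteoglycan Fmod at -1.74. Scx, the transcription factor that marks tendon progenitors, had a ratio of -1.25. Cartilage and fibrocartilage genes were lower for 15 of 22 members with a median of -1.59, including Col2a1, the main collagen of hyaline cartilage, at 215 and 28.1, Acan (aggrecan) at 92.7 and 14.1, and Col9a1 at -5.50. The chondrogenic factor Sox9 was higher, with a ratio of 0.51. By cluster, the tendon medians ran from -0.34 to 0.08. The cartilage medians ran from -1.48 in cluster 0 to 0.48 in cluster 3, with 3 of 6 clusters above 0. With each gene averaged within clusters the medians were -0.26 and -0.84. The cartilage value includes genes with too few UMIs to count as measured in most clusters, which can pull it down.

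Mineralisation and surface-layer genes went the other way. Bone formation genes were higher for 15 of 18 members with a median of 1.14, above all random lists, with bone sialoprotein (Ibsp) at 145 against 17.4 CPM, the osteocalcin gene Bglap2 at 2.95 and the bone morphogenetic protein gene Bmp2 at 1.26. Runx2, the master factor of osteoblasts, was lower at -0.77. Most Ibsp UMIs of the lineage with suspension lay in its 714 tenocyte-like cells, of which 600 were in cluster 21. By cluster, the list's median was 0.15 to 0.62 in 5 clusters and near 0 in cluster 0. Cluster 21 had too few cells without suspension to be run. Lubricin and hyaluronan layer genes were higher for 9 of 13 members with a median of 0.83, and 0.04 to 0.49 by cluster; the hyaluronan synthase gene Has2 was at 0.83 and Vcam1, an adhesion molecule, at -1.03. Matrix proteases and their inhibitors were lower for 14 of 22 members with a median of -0.28 (percentile 2.99), from the aggrecanase Adamts4 at 1.67 to the collagenase Mmp13 at -1.50.

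Lists tied to mechanical load split. Actin and contractile genes were lower for 13 of 15 members with a median of -0.68 (percentile 0.01), with smooth muscle actin (Acta2) at 31.2 and 10.3 CPM, Tagln at -1.75 and Cnn3 at -1.59. YAP/TAZ and strain targets had 14 of 22 members higher with a median of 0.26 (percentile 94.7). Its classical targets Ccn1 and Ccn2 were lower, at -1.15 and -1.08, and Igfbp3 was the member with the highest ratio. Focal adhesion and mechanosensing genes had 14 of 22 higher with a median of 0.14 (percentile 86.0), with the fibronectin receptor gene Itga5 at 1.09, the stretch-gated channel Piezo1 at 0.48 and Piezo2 at -0.78. TGF-beta and BMP response genes were lower for 15 of 20 members with a median of -0.39 (percentile 0.27), from the secreted glycoprotein Cthrc1 at -2.43 to the activin subunit Inhba at 1.29.

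Immediate-early genes, which tissue digestion also induces, were lower for 15 of 22 members with a median of -0.30 (percentile 1.86), with Dusp1 at -1.37, Jund at -1.34 and Egr1 at 0.11. By cluster the medians ran from -0.66 in cluster 0 to 0.19 in cluster 7. Cell cycle genes were higher for 17 of 19 members with a median of 0.68, though at low levels: the replication helicase gene Mcm6 was at 3.89 and 10.0 CPM and Mki67 at 2.41 and 5.00. By cluster the medians ran from -0.25 in cluster 7, where 11 of 19 were lower, to 1.18 in cluster 5, with 6 members higher and 6 lower in cluster 2. With doublets kept the cell cycle median was 1.29. The remaining lists were near the middle of random lists. Syndecans and heparan sulfate genes had 8 higher and 14 lower with a median of -0.08 (percentile 22.6), with Gpc1 at -1.40 and Gpc3 at 1.09. Glycolysis and hypoxia genes had 9 higher and 12 lower with a median of -0.09, with hexokinase gene Hk2 at 1.64. Oxidative phosphorylation genes had 6 higher and 12 lower (-0.06), heat shock genes 6 and 6 (0.01), and angiogenesis genes 8 and 8 (0.11).

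In total 11 of the 21 lists lay beyond percentiles 2.5 and 97.5 of random lists, limits chosen after seeing the data. Of these, 7 still did with each gene's ratio averaged within clusters, and the bone formation, lubricin, immediate-early and TGF-beta lists did not. Genes with few UMIs in a cluster enter that average too.

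The same question was asked of tenocyte-like cells, although cluster 0 held 95.5% of them without suspension and cluster 21, led by Angptl7, Clu, Fmod and Comp, held 84.0% of them with it. Interferon genes were lower for all 19 members with a median of -2.47, with Cxcl9 at 304 and 15.7 CPM and Isg15 at 87.4 and 5.32. Antigen presentation genes were lower for 14 of 15 (median -1.50). Mineralisation genes were far higher: Ibsp was at 1779 against 22.7 CPM, osteopontin (Spp1) at 1913 against 279, and 15 of 17 members of the bone list were higher with a median of 2.40. Tendon matrix genes were balanced, with 15 higher, 11 lower and a median of 0.06, unlike the pooled lineage, and cartilage genes were higher for 14 of 22 (median 0.51), with chondroadherin (Chad) at 865 against 75.3. Within cluster 0 alone cartilage genes were lower for 17 of 21 (median -1.48) and bone genes were higher for 6 and lower for 7, so these class values rest on setting cluster 21 against cluster 0.

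The named genes higher in tenocyte-like cells with suspension were the leptin receptor gene Lepr at a log2 ratio of 5.69 (5.13 to 6.30), Cdo1, which oxidises cysteine, at 5.29, Galnt15 at 5.04, the Wnt inhibitor Wif1 at 4.83 (14.1 and 402 CPM) and Cox4i2, a hypoxia-responsive subunit of cytochrome oxidase, at 4.59. Lower were Cxcl9 at -4.28, Isg15 at -4.04, the sulfatase family member Arsi at -3.52, Megf6 at -3.38 and the secreted Wnt modulator Sfrp2 at -3.26, which is among the leading genes of cluster 0. The IL-17, TNF and NF-kB list was lower for 19 of 24 members (median -1.09), with the chemokine genes Ccl7 at -1.88 and Cxcl5 at -1.74, yet Lcn2 was at 4406 against 572. Immediate-early genes were lower for 21 of 22 members (median -0.54). Median depth was 24548.5 UMIs per cell without suspension and 6923.5 with it.

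Fibroblast-like cells, 316 and 4200 in number, also had lower interferon genes (19 of 19, median -1.85) and lower antigen presentation genes (15 of 15, median -2.06), with H2-K1 at 1382 and 293 CPM. In cells thinned to 1000 UMIs the antigen presentation median was -1.42. Il6 was higher at 834 against 268. Named higher genes were Inmt, a methyltransferase that leads 1 fibroblast-like cluster, at 2.43, the collagen gene Col6a5 at 2.36, Galnt15 at 2.14, Snhg3 at 2.13 and the noncoding RNA Epb41l4aos at 1.80. In cells thinned to 1000 UMIs Col6a5 was at 1.47 and Epb41l4aos at 0.87, while Inmt (2.30), Galnt15 (2.61) and Snhg3 (1.83) moved less. Lower were Acod1, which makes itaconate in activated macrophages, at -3.83 (57.3 and 4.04 CPM, against 606 and 42.8 over all kept cells), the nonclassical MHC gene H2-Q7 at -3.19, Igtp at -2.94, the chemerin-binding receptor Ccrl2 at -2.90 (95.04 and 12.7 CPM) and Nos2, the inducible nitric oxide synthase, at -2.51. Acod1 and Ccrl2 are among the leading genes of neutrophil-like clusters 6 and 9, so free RNA may add to both; its part in these genes was not measured. Cell cycle genes were higher for 18 of 19 (median 0.90), glycolysis genes lower for 16 of 21 (median -0.50) and actin genes lower for 13 of 15 (median -0.51). Counts of these classes were scaled by totals, and the median of all genes in fibroblast-like cells was shifted by -0.08.

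Sdc1 and Sox5 address the question in the study's title, a SOX5-programmed fibroblast of the tendon sheath that carries SDC1. Sdc1 (ENSMUSG00000020592, chromosome 12, 8771323 to 8793715) encodes syndecan-1, a heparan sulfate proteoglycan of the cell surface. Sox5 (ENSMUSG00000041540, chromosome 6, 143828425 to 144781977) encodes a transcription factor of cartilage development. Both were highest in sheath or lining fibroblast-like cells, for which Sdc1 is also a fixed marker: Sdc1 was at 351 (Poisson interval 329 to 374) and 272 (266 to 279) CPM without and with suspension, and Sox5 at 258 (239 to 278) and 249.9 (244 to 256).

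Over the whole lineage Sdc1 was at 109.7 CPM (106 to 113) without suspension and 116.9 (115 to 119) with it, a log2 ratio of 0.09 whose sign depends on the setting. Within each class it was lower with suspension, at 93.3 and 88.2 in tenocyte-like and 61.2 and 48.0 in fibroblast-like cells, so the pooled value moves with the share of sheath cells. The tenocyte-like intervals overlap. In fibroblast-like cells the share with an Sdc1 UMI was 5.61% and 3.74% thinned to 1000 UMIs, but 6.77% and 6.84% at 2000. Sox5 was at 43.5 (41.3 to 45.8) and 95.1 (93.0 to 97.2) over the lineage, a log2 ratio of 1.13 that was 0.54 with doublets kept and 0.32 within clusters. The sheath or lining fibroblast-like class, where Sox5 was highest and similar in both libraries, was 6.10% of lineage cells without suspension and 18.5% with it. The pooled Sox5 value therefore also moves with the share of sheath cells. With doublets kept, the sheath or lining fibroblast-like class held 662 rather than 84 non-tail suspension cells. In that setting the naming of clusters changed as well. In tenocyte-like cells it was higher with suspension, at 35.3 against 20.3, and in fibroblast-like cells lower, at 30.4 against 44.7; in thinned cells these log2 ratios were 0.096 and -0.22. Over all kept cells Sdc1 had a ratio of -0.41, which was 0.17 in cells thinned to 1000 UMIs, and Sox5 was at 30.4 and 60.8 CPM.

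An Sdc1 UMI was found in 64.6% (62.0 to 67.1) of lineage cells without suspension and 40.1% (38.9 to 41.3) with it, at median depths of 22979.5 and 11375 UMIs. Thinned to 1000 UMIs per cell, leaving out 33 and 135 shallower cells, the shares were 8.49% and 8.02%. With clusters 4 and 25 added to the lineage, the thinned Sdc1 shares were 13.3% (11.8 to 14.8) and 8.70% (8.02 to 9.41). In that grouping a gap thus remained at equal depth. For Sox5 the shares in the lineage alone were 32.3% and 34.1%, or 3.35% and 6.17% after thinning. With clusters 4 and 25 the unthinned Sox5 order turned, at 46.7% and 36.1%, as it did with doublets kept (44.4% and 34.1%). T cell-like cells, at medians of 5480 and 3892.5 UMIs, had an Sdc1 UMI in 3.71% and 5.04% of cells and a Sox5 UMI in 1.01% and 1.46%. Among lineage cells thinned to 2000 UMIs, a Sox5 UMI was found in 10.3% (6.52 to 15.4) of cells with Sdc1 and 5.01% (3.81 to 6.46) without it in the non-tail suspension library. In the tail suspension library the shares were 21.6% (18.7 to 24.7) and 9.73% (8.91 to 10.6). Thinned to 1000 UMIs, the non-tail suspension shares were 4.39% and 3.25%, with overlapping intervals, and the tail suspension shares 14.0% (10.96 to 17.4) and 5.50% (4.90 to 6.14). Inside the sheath or lining fibroblast-like class at 2000 UMIs they were 45.7% (28.8 to 63.3) and 27.7% (15.6 to 42.6) without suspension and 35.0% and 38.2% with it, again with overlapping intervals. In tenocyte-like cells the order at 2000 UMIs was the other way, 2.00% with and 3.41% without Sdc1 in the non-tail suspension library. In the tail suspension library it was 3.49% and 6.09%. The shares with Sdc1 rest on 3 of 150 and 3 of 86 cells. At 1000 UMIs the tenocyte-like shares were 2.60% and 2.12% without suspension, and 0% and 2.48% with it. In fibroblast-like cells at 2000 UMIs the shares were 11.1% and 6.05%, and 7.22% and 4.72%. All these intervals overlap, so the pooled gap is not resolved within any class.

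Sdc1 was not particular to the sheath class. In cluster 4 it was at 304 and 271 CPM and in cluster 25 at 296 and 178. Osteoclast-like cells without suspension held 277 CPM, with a UMI in 98.0% of 51 cells. Mural-like cells held 243 and 136, cluster 11 held 154 and 69.2, and macrophage-like cells held 67.9 and 30.1. Sox5 in cluster 4 was at 95.3 and 82.8, and in cluster 25 at 79.9 and 83.0, while in macrophage-like cells it was at 0.581 without suspension, near background.

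**Figure D3:**
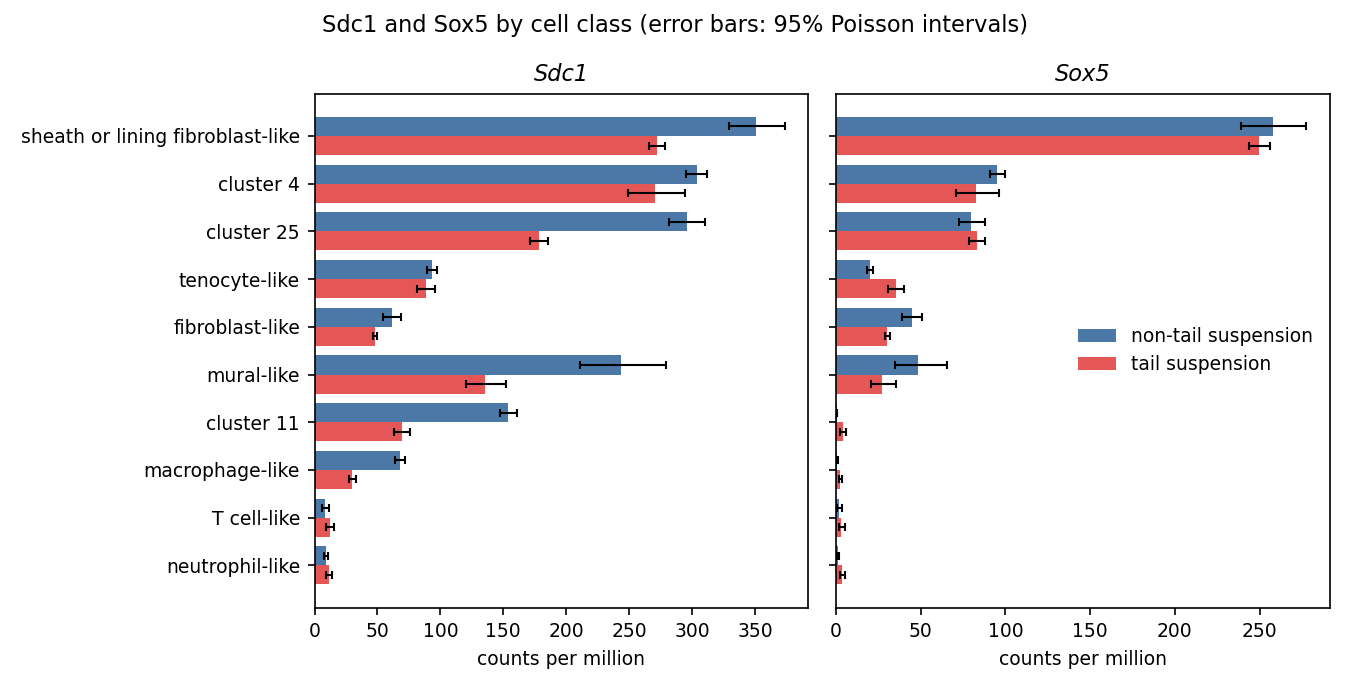
Sdc1 and Sox5 in CPM by cell class for the non-tail suspension and tail suspension libraries (1 library each), with 95% Poisson intervals as error bars. Both genes are highest in sheath or lining fibroblast-like cells, Sdc1 at 351 and 272 and Sox5 at 258 and 249.9, and Sdc1 is also high in clusters 4 and 25 and in mural-like cells.

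Summed over all kept cells, the comparison mixes expression with the change in cell makeup. Among the named genes, Prg4 was higher with suspension, at 20279.8 against 2721 CPM (log2 ratio 2.90), Igfbp3 at 2.86, the lipocalin Apod at 2.53, Scd1 at 2.48 and the collagen-processing enhancer Pcolce2 at 2.31. Lower were Ly6i, a surface protein of myeloid cells, at -4.81, Rsad2 at -3.99, Acod1 at -3.82 (606 and 42.8 CPM), the niacin receptor gene Hcar2 at -3.78 and the noncoding RNA Mirt2 at -3.55. These 10 genes, named on the same condition, kept their direction in the other 5 alternative settings, and Apod was at 3.75 in thinned cells. Tendon matrix genes were lower for 19 of 26 members (median -0.32), although the fibroblast-lineage share was larger with suspension. The interferon list had a median of -2.15, and the glycolysis list was lower for 16 of 21 members with a median of -0.64.

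In neutrophil-like cells the interferon list had its lowest median of the classes compared, -3.45, with all 19 members lower. The guanylate-binding protein gene Gbp4 had 2591 UMIs without and 7 with suspension, a log2 ratio of -7.21 (-8.52 to -6.16), Ly6i was at -5.28 and the immunity-related GTPase Ifi47 at -4.77. Cytokine genes were also lower: Il1b at 9314 and 1728 CPM, and the neutrophil chemoattractant Cxcl3 at 1006 and 144. Immediate-early genes were lower for 20 of 22 members (median -1.57). Stfa3, a cysteine protease inhibitor, was higher at 3121 against 135, as was Crip1 at 785 against 114, and the granulocyte alarmin S100a8 had a ratio of 1.77. The clusters differed: clusters 6, 8 and 9 held most of these cells without suspension, and clusters 10 (51.4%) and 8 (36.4%) with it. Stfa3 and S100a8 are among the leading genes of cluster 10, and Il1b of clusters 6 and 9. Neutrophil-like cells were not compared by cluster, so these ratios include the change in cluster mix. Angptl7, the third named higher gene at 3.23, was present in T cell-like cells with a ratio of 3.44 and is a tendon transcript.

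In macrophage-like cells interferon genes were lower with suspension. The haemoglobin scavenger receptor gene Cd163 was at 544 against 22.6 CPM with suspension, the water channel Aqp1 at 104 against 4.27 and Fgfr1 at 77.7 against 6.14. The serpin Serpina3g had a log2 ratio of -3.97, the channel gene Calhm6 -3.74 and Cxcl9 -3.25, and all 19 interferon genes were lower (median -1.48). Cluster 17 held 58.9% of these cells without suspension and 2.42% with it, the rest being in cluster 13. Monocyte-like cells had lower Upp1 (uridine phosphorylase) at -3.24, Ass1 of arginine synthesis at -3.06 and Ly6i at -2.98, with 18 of 19 interferon genes lower (median -2.09). Higher were the adhesion receptor gene Cd2 at 3.02, Crip2 at 2.91 and Spata7 at 2.87.

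In T cell-like cells, Ifng, the gene of interferon gamma, was at 295 CPM without suspension and 24.9 with it, a log2 ratio of -3.57 (-3.86 to -3.29). Il17a, the effector cytokine of the IL-17 pathway, was at 276 and 62.6, a ratio of -2.14 (-2.34 to -1.95), and the keratin gene Krt83 was at -1.96. The class joins clusters 12, 14 and 16 in unlike parts: cluster 12 held 344 of 593 cells without suspension and 375 of 892 with it, and these genes were not compared by cluster. The IL-23/IL-17 axis list was lower for 13 of 17 members (median -0.54, percentile 0.13), with Trdc of the gamma-delta receptor at -1.52 and Il23r at -1.16. Il22 was among the 4 members that were higher, at 64.4 with and 27.8 without suspension, while Il17f was lower at 105 with and 127 without it. Interferon genes were lower for all 18 measured members (median -1.07). Higher named genes were Mt2 (metallothionein) at 425 against 56.6, the protease inhibitor Serpina3n at 76.6 against 8.42, and Angptl7. Serpina3n was at 1605 and 799 in fibroblast-lineage cells, and the part of free RNA in it was not measured.

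**Figure D4:**
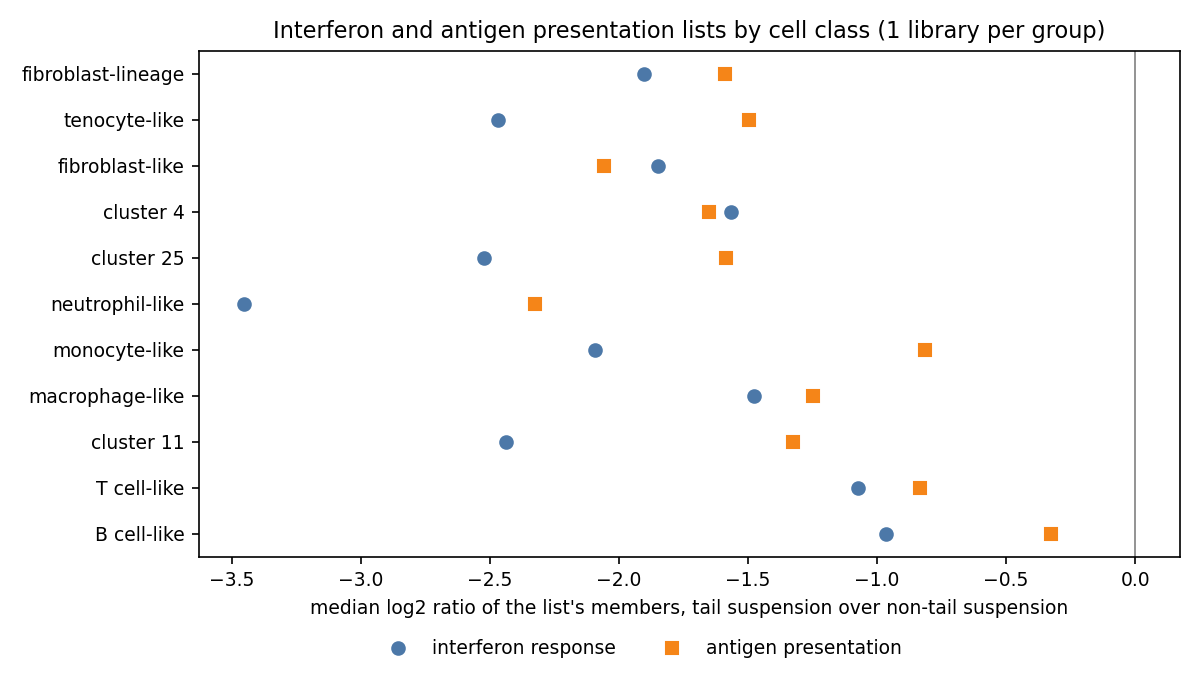
Median log2 ratio (tail suspension over non-tail suspension, 1 library each) of the interferon response and antigen presentation lists in each cell class compared. All medians shown are below 0, from -3.45 for the interferon list in neutrophil-like cells to -0.33 for antigen presentation in B cell-like cells.

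The interferon list was also lower in cluster 11 (-2.44), cluster 25 (-2.52), cluster 19 (-1.81), cluster 4 (-1.57) and B cell-like cells (-0.97). In thinned cells the cluster 4 median was -0.39. Antigen presentation medians were -2.33 in neutrophil-like, -1.25 in macrophage-like, -0.82 in monocyte-like and -0.83 in T cell-like cells. For B cell-like cells that median was -0.33, at percentile 25.3 of random lists. Focal adhesion genes were higher in macrophage-like (17 of 20, median 0.84) and monocyte-like cells (15 of 19, median 0.77), where tendon matrix transcripts were higher too (medians 1.12 and 1.06). No class turned its direction for the interferon list under median-of-ratios scaling or thinning. The median of all genes was shifted by 0.21 in macrophage-like, -0.23 in B cell-like, -0.11 in T cell-like cells, 0.12 in cluster 11 and 0.11 over all kept cells; the interferon medians exceed these shifts.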

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

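Of the tests in this part, all but the comparison of stromal genes in immune cells were chosen after the result was seen. Sox5 went opposite ways in 2 fibroblast classes: its log2 ratio of tail suspension over non-tail suspension was 0.80 in tenocyte-like cells and -0.56 in fibroblast-like cells. Tenocyte-like cells were mostly cluster 0 without suspension and cluster 21 with it. Thinned to 1000 UMIs, a Sox5 UMI was found in 2.15% and 2.30% of tenocyte-like cells and 3.16% and 2.89% of fibroblast-like cells (non-tail suspension first), with overlapping intervals. The difference was not tested, since each class comes from 1 library per group. Haemoglobin genes were left out of the comparisons, and there Hbb-bs, the adult beta-globin of red cells, was at 474 CPM with suspension and 57.0 CPM without it.

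Interferon and antigen presentation genes were lower in fibroblast-lineage cells of the tail suspension library, with a median log2 ratio of -1.75 over both lists. RNA freed by the many immune cells of the non-tail suspension library is argued against for most of the 29 genes outside MHC class II. In the pooled lineage, 31 immune markers were found at a median of 3.02% of their immune level. RNA at that share gives a median of 8.58% of the gap between libraries, and under 25% for 25 of the 29. The others are Nlrc5, Gbp2, Rsad2 and Ifit2. For Rsad2 and Ifit2 it gives 57.6% and 106.8%, so free RNA stays open for these genes. For the 5 MHC class II genes the same share gives 119.6% of the gap, so free RNA could account for all of their difference. Cell makeup is argued against by a highest within-cluster median of -1.10 over 6 of the 8 clusters, the other 2 having too few cells, and depth per cell by a median of -1.64 in cells thinned to 1000 UMIs. Of the 6 clusters, cluster 0 had 932 cells without suspension and the rest had 59 to 96 each. The share of free RNA was not measured by cluster, so its part in these medians is not known. Suspension and any other difference between the libraries cannot be told apart with 1 library per group, so an effect of unloading on interferon signalling stays an untested hypothesis.

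Tendon matrix genes were lower in pooled fibroblast-lineage cells, with a median log2 ratio of -1.01. The list's median, taken in each cluster, averaged -0.18, from -0.34 to 0.08, so a different mix of clusters may account for most of the pooled value. The clusters were built in part from these genes, and a change in cells that also moves them to another cluster cannot be told apart from a change in makeup. Suspension as such was not tested here.

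Stromal genes such as Prg4, Dcn and Col3a1 were present in T cell-, monocyte- and neutrophil-like cells of the tail suspension library. Free RNA from stromal cells needs the same ratio for every gene, and over 45 stromal genes the log2 ratio of T cell-like to monocyte-like CPM had an interquartile range of 0.66 around a median of 0.72. For most of these genes the values are consistent with free stromal RNA. Angptl7, a named gene of T cell- and neutrophil-like cells, had a ratio of 2.43, with Fmod at 2.72 and Chad at 2.95, so a common source of free RNA leaves these tendon genes open. No biological explanation was tested for this pattern.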

How the results depend on the processing

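Single genes were judged against their counting interval, and list medians by a fixed distance from the main median. Among both, 334 values under the alternatives fixed beforehand stayed within these limits, 174 moved beyond them and 7 reversed. Under alternatives added after seeing the data (within clusters, and with clusters 4 and 25) these counts were 35, 49 and 2. A change of sign is counted for single genes and for lists beyond the percentile limits, and all 9 were of Sdc1. Among the other lists, whose signs are not counted, the IL-23/IL-17 median of 0.43 was -0.52 with each gene averaged within clusters. Genes with few UMIs in a cluster can pull that average down. In the fibroblast lineage the Sdc1 log2 ratio of 0.09 became -0.034 in cells thinned to 1000 UMIs, -0.14 as a mean over cells and -0.51 with at most 10% mitochondrial UMIs. It was -0.59 with doublets kept, -0.53 at resolution 0.5, -0.53 with clusters 4 and 25, and -0.093 within clusters. Over all kept cells its -0.41 became 0.17 when thinned and 0.12 as a mean over cells. The 20 and 10 named genes of the fibroblast lineage and of all kept cells kept their direction, which median-of-ratios scaling and thinning to 1000 UMIs could not have changed, since keeping the sign under both was part of the rule for naming. Of the 11 lists beyond the percentile limits, 7 were so within clusters and 8 to 11 under the other alternatives. The fibroblast-lineage and neutrophil-like share differences kept their direction, but sizes moved; at resolution 2.0 all 4 shares stayed within their intervals. Shares are given as non-tail suspension then tail suspension. For the fibroblast lineage they were 16.2% and 41.0% with at least 500 genes, 16.5% and 47.6% with at least 1000, 18.2% and 45.7% with at most 10% mitochondrial UMIs, 18.4% and 47.7% with doublets kept, 19.0% and 46.7% at resolution 0.5, 8.57% and 45.4% with each library clustered on its own, and 19.1% and 47.0% with clusters 4 and 25. Neutrophil-like shares were 25.8% and 5.91% with at least 1000 genes, and 49.8% and 10.1% with at most 10% mitochondrial UMIs; in the tail suspension library alone they moved to 10.1% with at least 500 genes or doublets kept and to 10.2% at resolution 0.5 or clustered on its own. Cells with an Sdc1 UMI were 8.49% and 8.02% when thinned to 1000 UMIs, 15.4% and 13.4% at 2000, 44.7% and 24.6% with at least 2 UMIs, 72.0% and 41.7% with doublets kept, and 74.2% and 43.7% with clusters 4 and 25. With these clusters and thinning together, they were 13.3% and 8.70% at 1000 UMIs and 22.8% and 14.7% at 2000. For Sox5 they were 3.35% and 6.17% at 1000 UMIs, 5.83% and 11.3% at 2000, 16.6% and 20.2% with at least 2 UMIs, 46.7% and 36.1% with clusters 4 and 25, and 44.4% in the non-tail suspension library with doublets kept. Thinning and a minimum of 2 UMIs lower detection by construction. For the other moves the cause was not tested, but the naming of clusters changed with the setting. The sheath or lining fibroblast-like class held 84 non-tail suspension cells, but 662 with doublets kept, 565 with at most 10% mitochondrial UMIs and 734 at resolution 0.5. Unnamed cluster 4 held 564 such cells. A filter's own effect on Sdc1 and Sox5 cannot be told apart from this naming. No paired analysis was possible because each group is 1 library, and for the same reason no library could be left out in turn. Depth limits the smaller classes: osteoclast-like cells with suspension numbered 3, and B cell-like cells without it 102.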

Other observations

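B cell-like cells differed in precursor and proliferation genes. Vpreb1 and Igll1, which encode the surrogate light chain of precursor B cells, had 199 and 130 UMIs in 102 cells without suspension and 0 in 334 cells with it, log2 ratios with upper interval limits of -6.23 and -5.61. Only 11.8% and 12.7% of the 102 cells held them, and in cells thinned to 1000 UMIs the ratios were -4.26 and -2.67 with a 0 set to 3 UMIs. The histone gene Hist1h1b was at -6.07, and all 19 measured cell cycle genes were lower with suspension (median -3.20). The labels do not say how much bone marrow, where B cells develop, was dissected with the enthesis, and its share was not tested. Gpr183, which guides B cells in lymphoid tissue, was higher at 4.61 (3.22 to 6.51) from 4 UMIs against 137, and at 2.61 in cells thinned to 1000 UMIs. It was followed by Serpina3n at 3.67 (6 and 107 UMIs, 2.88 thinned) and Ccl2 at 3.14 (2.06 thinned). Both are abundant in fibroblast-lineage cells, with Serpina3n at 1605 and Ccl2 at 2892 CPM there with suspension, so whether B cell-like cells express them is left open; free RNA was not measured for them.

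Unnamed cluster 11, with MHC class II genes in front, had higher Ccl17. This gene, whose chemokine attracts T cells, was at 2071 CPM with suspension against 28.6 CPM without it, a log2 ratio of 6.18 (6.03 to 6.33). Rnase2a had 419 UMIs against 2, a ratio of 8.79 (6.93 to 11.84; 4.34 in cells thinned to 1000 UMIs), and Anxa8 a ratio of 4.79. Ly6i was at -4.63, Calhm6 at -3.89 and Serpina3g at -3.68. In unnamed cluster 4, a mostly non-tail suspension cluster, Tnfsf8, Hmcn1 and Ctla2a were higher with suspension at 3.12, 2.68 and 2.66. Lower there were the angiotensin receptor gene Agtr2 at -5.20 (-7.48 to -3.64, 3 UMIs with suspension; -1.16 in cells thinned to 1000 UMIs), the retinoic acid enzyme gene Aldh1a2 at -4.59 and the Wnt modulator Sfrp4 at -4.57. In unnamed cluster 25, Ccl11 was higher at 3.26, Ccdc3 was at 77.3 CPM against 9.02 and Spata7 at 156 against 18.2, and the interferon-inducible genes Iigp1, Igtp and Isg15 were lower at -4.70, -4.65 and -4.07. In cells thinned to 1000 UMIs Ccl11 was at 1.82, Ccdc3 at 2.31 and Spata7 at 2.82. Iigp1, Igtp and Isg15 were then at -5.68, -2.56 and -3.56. In unnamed cluster 19, whose leading genes mix the granule genes Prtn3 and Mpo with the keratinocyte gene Lgals7, Hes1 and Dlx2 had 1 UMI each without suspension and 347 and 207 with it, ratios of 8.12 (5.63 to 13.43) and 7.38 (4.88 to 12.69). Mt4 had 0 and 467 UMIs, a ratio with a lower interval limit of 6.66. In cells thinned to 1000 UMIs, where few UMIs of such genes remain and a 0 is set to 3, the ratios of these 3 genes were 2.44, 0.90 and 1.49. Slc9b2 was lower at -6.78 (-9.83 to -4.90; -2.42 thinned), Cxcl13 at -3.83 and Bdh2 at -3.77.

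Tendon matrix transcripts were higher with suspension in immune classes, for 23 of 23 measured members in T cell-like cells (median 1.37), 22 of 23 in macrophage-like cells (1.12) and 22 of 22 in monocyte-like cells (1.06). Free stromal RNA, weighed above for T cell- and monocyte-like cells, may account for such values. It was not tested in macrophage-like cells. Glycolysis and hypoxia genes were lower in neutrophil-like (median -1.12), monocyte-like (-0.71), cluster 11 (-0.65) and T cell-like cells (-0.57). Oxidative phosphorylation genes were higher for 15 of 18 members in neutrophil-like cells (median 0.45).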
